A study of Homo sapiens with 14 samples.

How the data were processed

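The series holds RNA-seq of IMR90 fibroblasts, untreated (2 libraries) or exposed to 20 uM ddC for 24, 48, 72 or 96 h (3 libraries each). Polyadenylated RNA was prepared with a stranded mRNA kit, per the labels' protocols. Reads were aligned with STAR 2.5.3a to hg19 and quantified with HOMER, per the submitters' processing notes, which give neither a strand setting nor a filter. The deposited table holds raw counts per gene, 27142 genes in 14 columns, and every column was joined to its sample by its title. The values were integers with 0 repeated genes and 0 genes from the mitochondrial chromosome. Counts on VIM-AS1 were 0.155% of those on VIM on the other strand, and SNX22 had 0.309% of those on PPIB, so the counts were read as strand-specific. Coordinates are those of the table, on hg19. A separate annotation on another genome build was used only for GC content, transcript length and which genes overlap on opposite strands.

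Group, test, thresholds, gene lists, rule for naming genes and the first set of other analyses were fixed before the data were examined. Gene tests used edgeR 4.0.16 in R 4.3.3, with TMM factors (0.971 to 1.02), filterByExpr defaults (minimum count 10, minimum total count 15), and a robust quasi-likelihood fit of all 14 libraries with 1 mean per group. Each time was compared with untreated cells, each time with the one before, 96 h with 24 h, and the 4 treated times jointly. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, two-sided. "Separated" means that every library of one group lay beyond every library of the other in CPM. Expression in CPM is counts divided by the TMM-scaled library total, times 1e6. The SE of a fitted log2 fold change was derived from its test. It is the size of the change divided by the square root of the quasi-likelihood F statistic.

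Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 3 and a preset correlation of 0.01. Adjusted p was taken over 27 lists and 4 times against untreated cells together (108 tests), and over the lists of 96 h against 24 h apart. The smallest list tested had 5 genes. The lists were nuclear complex I subunits, nuclear complex II to V subunits, mitochondrial ribosomal proteins, mtDNA replication, transcription and maintenance, nucleotide metabolism, ATF4 targets, mitochondrial chaperones and proteases, ER stress, cytosolic heat shock, interferon-stimulated, NF-kB and secreted inflammatory genes, p53 targets, DNA replication and G1/S, G2/M, cholesterol, fatty acid synthesis, fatty acid oxidation, glycolytic, hypoxia-response, tricarboxylic acid cycle, NRF2 targets, immediate early, collagens and matrix, contractile, lysosome and autophagy, cytosolic ribosomal proteins and ribosome biogenesis. Lists overlapped in a few genes, such as GDF15 and SESN2 in those of ATF4 and p53. Markers of fibroblasts, epithelium, endothelium and blood cells served to look for other cell types.

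Genes named for each time against untreated cells were the 6 largest rises and 6 largest falls among called genes with an average log2 CPM of at least 1 and separated libraries, the 3 members with the smallest p in the direction of each called list, and 17 fixed genes, 1 of which is not reported here. For 96 h against 24 h they were the 6 largest rises and 6 largest falls. Genes named outside this rule are said to be so, or are list members, markers or genes of consecutive times, all of which were singled out after their values were seen. Y-linked genes and the X-inactivation transcripts were left out.

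Precision was checked on data simulated at these depths. With 96 h against untreated cells, 28%, 74%, 90% and 94% of genes changed by 1.25-, 1.5-, 2- and 4-fold were recovered, and 9 of 13131 unchanged genes were called. A simulated list of 40 genes changed by 1.1-fold at 24 h gave an adjusted p of 1.46e-06 with 0 of its genes called, and 0 of 81 unchanged list tests were called. Genes were drawn independently of each other, with no structure among libraries such as that of nuclear RNA. These rates may therefore not hold in the real data, where genes can be correlated. Correlations and overlaps between times against the same untreated libraries were set against 20 simulations with no effect of ddC.

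The analyses repeated in other ways, as chosen at the outset, used median-ratio size factors in edgeR, DESeq2 1.42.0, limma-voom, no filter on low counts, the replicate number as a block, only the compared groups in the fit, leaving out each library in turn, an estimated correlation in camera, and the rotation test fry. Leaving out an untreated library leaves 1, which is then assumed to vary like the libraries of the other groups. Alternatives added after seeing the data were a nuclear RNA score as a covariate (mean log2 CPM of MALAT1, NEAT1, MEG3 and KCNQ1OT1), the library set as a term, both together, and only the 7 libraries of one set. The antisense index rests on 45 pairs of an abundant gene of at least 200 CPM and an opposite-strand neighbour, SERF2 being paired with both MIR1282 and SERINC4. Each neighbour had at least 10 reads and under 0.1% of those of its abundant partner. The index is the reads of the neighbours per 1000 reads of the abundant genes. The library set is an index above or below 0.4. For each regrouping of the treated libraries, the share of the variance of the nuclear RNA score and of the antisense index between groups was taken. To compare 96 h libraries with 72 h within a set, genes were called without the 96 h library under test, and that library was then compared with the 72 h mean. RNA from mtDNA was not analysed here because the table held 0 of its 15 listed genes.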

Results

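Messenger RNA was measured by stranded sequencing of polyadenylated RNA in IMR90 cells, an established line of human fetal lung fibroblasts. Cells were exposed to 20 uM 2',3'-dideoxycytidine (ddC), a chain-terminating cytidine analog that blocks replication of mitochondrial DNA (mtDNA), for 24, 48, 72 or 96 h. Each time had 3 libraries, and untreated cells had 2. The study's design text gives the untreated cells as 0 h, whereas their sample labels name a water vehicle and 4 days, so the time they spent in culture is uncertain. Total counts per library ranged from 9398703 to 12147402, and 13371 of the 27142 genes in the table were tested. The table held 0 of 15 listed genes carried on mtDNA itself, so mtDNA-encoded RNA was not analysed here. Values below are fitted log2 fold changes ± SE with n = 3 treated and 2 untreated libraries, unless other groups are named.

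Several measures differed among libraries. MALAT1, a nuclear long noncoding RNA, ranged from 52.1 to 409 CPM (counts scaled to the library total) and varied as widely within groups, from 52.2 to 356 CPM among the 24 h libraries. An antisense index was taken over 45 pairs of an abundant gene and an opposite-strand neighbour, as the neighbours' reads per 1000 reads of the abundant genes. It parted the libraries into 7 with a lower index (0.291 to 0.368) and 7 with a higher one (0.408 to 0.494). The index rests on 105 to 202 opposite-strand reads per library. The nearest libraries of the 2 sets were 24 h replicate 1 (0.368, 115 reads) and 96 h replicate 2 (0.408, 169 reads). These may differ by counting error alone, so a clean division is not shown. The lower-index libraries were the 2 untreated, the 3 at 24 h and replicates 1 and 2 at 48 h. The higher-index libraries were replicate 3 at 48 h and all libraries at 72 h and 96 h, so comparisons of 72 h or 96 h with untreated cells or with 24 h also compared these sets. Only 48 h held libraries of both sets, so results below with the library set as a term rest on 1 library, 48 h replicate 3. Among fibroblast markers, COL1A1 stood at 15694 CPM or more and VIM at 4994 CPM or more in every library, though S100A4 lay at 4.58 to 7.46 CPM. Among markers of other cells, CDH1, PECAM1 and CD3E had 0 counts throughout. The epithelial KRT18 (39.5 to 61.3 CPM), the endothelial TEK (34.0 to 45.7 CPM) and the blood cell marker CD68 (43.0 to 60.8 CPM) were expressed in every library.

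**Figure D1:**
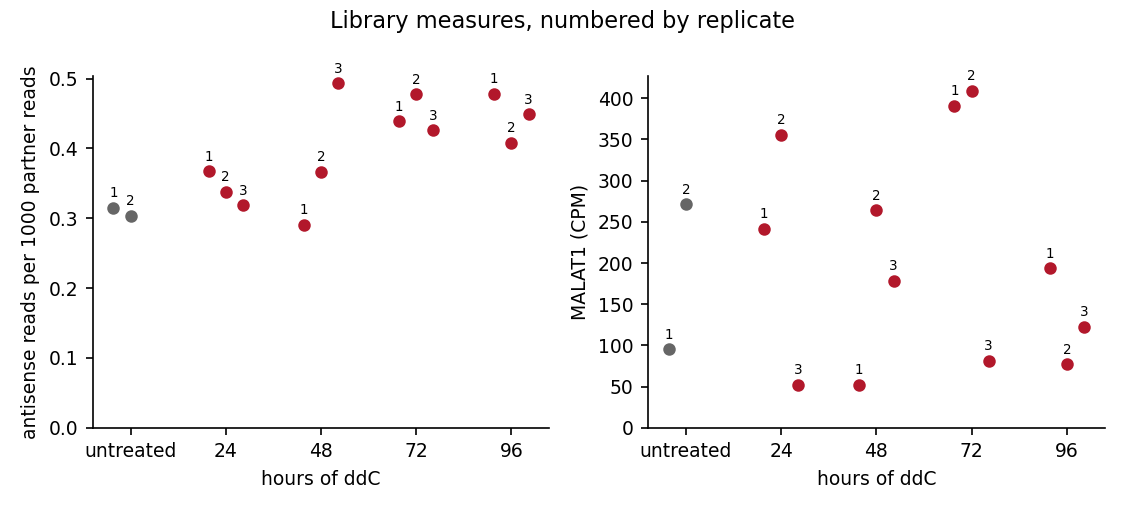
Antisense index (opposite-strand reads per 1000 reads of the abundant genes of 45 pairs) and MALAT1 (CPM) in each of the 14 libraries, grouped by hours of ddC and numbered by replicate. The index ran from 0.291 to 0.368 in 7 libraries and from 0.408 to 0.494 in the other 7, while MALAT1 spread from 52.1 to 409 CPM with no such division. With 105 to 202 opposite-strand reads per library, the gap in the index may lie within counting error.

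The comparison of 24 h with untreated cells asked which transcripts respond early in ddC exposure. Genes activated by the stress-responsive transcription factor p53 were higher as a group, and genes of DNA replication and S-phase entry were lower, with no single gene passing the test. Of 38 tested p53 targets, 35 lay above 0, with a median log2 fold change of 0.17. Among them, CDKN1A, the cell cycle inhibitor p21, stood at 0.42 ± 0.08 (adjusted p = 0.378), FDXR, a mitochondrial ferredoxin reductase, at 0.55 ± 0.12 (adjusted p = 0.980), and BBC3, the proapoptotic protein PUMA, at 0.63 ± 0.15 (adjusted p = 0.980). Of 52 DNA replication and G1/S genes, 48 lay below 0, with a median of -0.15. Its members included E2F2, an S-phase transcription factor, at -0.81 ± 0.19 (adjusted p = 0.980) and MCM7, a subunit of the replicative helicase, at -0.19 ± 0.06 (adjusted p = 0.999). Adjusted over the list alone, 10 p53 targets and 2 DNA replication genes passed. All 3 libraries at 24 h lay beyond both untreated libraries in the mean of each of these lists.

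In the competitive list test, adjusted p was 1.96e-18 for p53 targets and 4.62e-16 for DNA replication genes. Both held with an estimated correlation, at adjusted p = 5.75e-05 and 0.0265. So did interferon-stimulated genes, higher by a median of 0.08 (adjusted p = 0.00168, and 0.0270 with an estimated correlation), and ribosome biogenesis genes, at a median of -0.08 (adjusted p = 1.11e-05, and 0.0367 with an estimated correlation). In these lists, the interferon-response regulator IRF1 stood at 0.39 ± 0.11, the antiviral gene IFIT1 at 0.02 ± 0.17 and the rRNA-processing factor RRP12 at -0.28 ± 0.12, and 0 members of either passed. Another 4 lists were called by camera with the preset correlation but not with an estimated one. They were targets of ATF4, the transcription factor of the amino acid response (median 0.06, adjusted p = 5.39e-06, and adjusted p = 0.0848 with an estimated correlation), nuclear-encoded complex I subunits (0.07, 0.0191, and adjusted p = 0.829 with an estimated correlation), nucleotide metabolism genes (-0.05, 0.0120, and adjusted p = 0.354 with an estimated correlation) and G2/M genes (-0.04, 0.00663, and adjusted p = 0.829 with an estimated correlation). The complex I call ended without 24 h replicate 1, 24 h replicate 3 or untreated replicate 2 (highest adjusted p = 0.541). The nucleotide call ended without 24 h replicate 2 or untreated replicate 1 (0.274), and the G2/M call without 24 h replicate 2, 24 h replicate 3 or untreated replicate 2 (0.299). The replicate number as a block also ended the complex I call (camera adjusted p = 0.190). Of these 4 lists, the rotation test fry called ATF4 targets alone (adjusted p = 0.0367). For single genes, edgeR called 0, with 457 genes at an unadjusted p under 0.05 where chance alone would give 669. DESeq2 called 1 and limma-voom 0, and edgeR called 1 gene without 24 h replicate 1 or without 72 h replicate 3.

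At 48 h, the question was whether these early changes grew. CDKN1A (NM_001220778; hg19 chromosome 6, 36646487 to 36655116) was the 1 gene called, and it rose from 439.7 ± 14.5 CPM (SD, n = 2) to 643 ± 31.2 CPM (SD, n = 3), a log2 change of 0.55 ± 0.08 (adjusted p = 0.0106). Other p53 targets that did not pass included BBC3 at 0.79 ± 0.14 (adjusted p = 0.0784) and SPATA18 at 0.70 ± 0.15 (adjusted p = 0.282). The p53 list was higher, with 34 of 38 members above 0, a median of 0.18 and 17 members higher when adjusted over the list alone (adjusted p = 1.15e-18, and 5.75e-05 with an estimated correlation). DNA replication genes were lower by the preset test (median -0.08, adjusted p = 5.39e-06, and adjusted p = 0.174 with an estimated correlation), with MCM6, another helicase subunit, at -0.20 ± 0.07. edgeR gave 804 genes at an unadjusted p under 0.05. DESeq2 called 1 gene and limma-voom 0, and 0 genes were called without 48 h replicate 1, untreated replicate 1 or untreated replicate 2 (CDKN1A at most adjusted p = 0.523). The count was 2 without 24 h replicate 1, 24 h replicate 3, 48 h replicate 3 or 72 h replicate 3.

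Another 5 lists were called at 48 h with the preset correlation alone. Nuclear complex I subunits were higher (median 0.09, adjusted p = 3.03e-04), as were complex II to V subunits (0.04, 0.0276) and mitochondrial ribosomal proteins (0.04, 0.0219). With an estimated correlation, adjusted p = 0.695, 0.829 and 0.829. Ribosome biogenesis genes (-0.06, 0.00164) and collagens and extracellular matrix (-0.06, 0.0371) were lower, with adjusted p = 0.106 and 0.829 with an estimated correlation. Members were close to 0: the complex I subunit NDUFC1 stood at 0.24 ± 0.09, the cytochrome oxidase subunit COX7C at 0.22 ± 0.08 and the basement membrane collagen COL4A1 at -0.18 ± 0.06. The complex I call ended without 48 h replicate 1 (adjusted p = 0.0875), and the calls of complexes II to V and of mitochondrial ribosomal proteins without 48 h replicate 1 or untreated replicate 2 (at most 0.842 and 0.884). The latter 2 calls also ended with the nuclear RNA score as a covariate and with the replicate number as a block (camera adjusted p = 0.251 and 0.237). The ribosome biogenesis call ended without untreated replicate 2 (0.0833). The matrix call ended without any 1 of 24 h replicate 1, 48 h replicates 1 and 3, 96 h replicates 2 and 3 or either untreated library (at most 0.245), and with the library set as a term (0.245). The number of lists called at 48 h was 3 without 48 h replicate 1 and 4 without untreated replicate 2.

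At 72 h, 24 genes passed the test, 19 higher and 5 lower. The largest rise was that of ACTA2, smooth muscle alpha-actin (hg19 chromosome 10, 90694831 to 90751154), from 473 ± 20.7 CPM (SD, n = 2) to 790.4 ± 94.1 CPM (SD, n = 3), a log2 change of 0.74 ± 0.08 (adjusted p = 1.08e-04). The next were RDH10, a retinol dehydrogenase (0.64 ± 0.09, adjusted p = 0.00420), CDKN1A (0.61 ± 0.08, adjusted p = 9.90e-04), MAMDC2 (0.61 ± 0.12, adjusted p = 0.0332), the adhesion adaptor LIMS2 (0.60 ± 0.10, adjusted p = 0.0166) and FDXR (0.58 ± 0.12, adjusted p = 0.0450). The 5 that fell were FAM111B, a member of a serine protease family (-0.58 ± 0.09, adjusted p = 0.0119), SSX2IP (-0.47 ± 0.08), the growth factor HGF (-0.39 ± 0.07), the linker histone H1F0 (-0.37 ± 0.07) and DPYSL3 (-0.29 ± 0.06, largest adjusted p = 0.0289). Among members of called lists, the actin-binding protein TAGLN rose by 0.46 ± 0.07 (adjusted p = 0.00602), ACTG2, a smooth muscle gamma-actin, by 0.45 ± 0.07 (adjusted p = 0.00602), the elastic fiber protein ELN by 0.44 ± 0.08 (adjusted p = 0.0332) and STC2, a secreted glycoprotein, by 0.29 ± 0.05 (adjusted p = 0.0226). Of the genes fixed beforehand, GDF15, a stress-induced secreted factor, stood at 0.68 ± 0.15 (adjusted p = 0.0654) and TFAM, which packages mtDNA, at -0.19 ± 0.09 (adjusted p = 0.682). At an unadjusted p under 0.05 there were 968 genes.

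Calls at 72 h depended on single libraries. The count was 4 without 72 h replicate 1, 6 without 72 h replicate 3, 2 without untreated replicate 1 and 1 without untreated replicate 2. It was 57 with DESeq2 and 7 with only the compared groups in the fit. The replicate number as a block gave 25, with 22 of the 24 among them. With the library set as a term it was 0, although all 24 genes kept their sign, with a median of 0.54 against 0.45, and the calls ended because the median SE grew to 0.13 from 0.08. With that term and the nuclear RNA score together 127 genes were called, 19 of the 24 among them. Of the 15 genes just named as changed, only ACTA2 kept its call without any 1 library (at most adjusted p = 0.0314). CDKN1A lost it without untreated replicate 2 (0.0899), RDH10 without either untreated library (at most 0.226), ACTG2 without either untreated library (at most 0.286) and with only the compared groups in the fit, and TAGLN without either untreated library or 72 h replicate 1 (at most 0.286). FAM111B, SSX2IP, HGF, STC2 and LIMS2 lost it without either untreated library or 72 h replicate 1 or 3 (at most 0.282, 0.346, 0.390, 0.413 and 0.368), and all of these but LIMS2 with only the compared groups. H1F0 lost it without either untreated library or 72 h replicate 1 or 2 (at most 0.346), DPYSL3 without either untreated library, 72 h replicate 1 or 3 or 96 h replicate 1 (at most 0.445), and both with only the compared groups. MAMDC2 lost it without either untreated library, any 1 of the 3 at 72 h, 48 h replicate 1 or 96 h replicate 3 (at most 0.445), and FDXR without either untreated library, any 1 of the 3 at 72 h or at 96 h or 48 h replicate 1 (at most 0.495), and both with limma-voom and with only the compared groups. ELN lost it in the ways of FAM111B, without 48 h replicates 1 or 2 or 96 h replicate 1 (at most 0.491), and with limma-voom.

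Of 10 lists called at 72 h, 5 held with an estimated correlation. The p53 targets had a median of 0.20, with 2 of 38 rising and 22 when adjusted over the list alone (adjusted p = 4.41e-19, and 5.75e-05 with an estimated correlation). Contractile genes had a median of 0.13, with 5 of 29 rising and 12 over the list alone (7.58e-13 and 0.0367), and ATF4 targets 0.13, with 1 of 51 rising and 10 over the list alone (8.33e-13 and 0.0177). Hypoxia-response genes had a median of 0.14 with 0 of 25 rising (3.03e-04 and 0.0409), and DNA replication genes -0.15 with 0 of 52 falling and 16 over the list alone (1.57e-13 and 0.0367). Matrix genes (0.12, adjusted p = 7.35e-06) and glycolytic genes (0.07, 0.00814) were higher by the preset test, with adjusted p = 0.338 and 0.369 with an estimated correlation. Ribosome biogenesis (-0.07, 7.80e-04), nucleotide metabolism (-0.07, 0.0200) and targets of the antioxidant regulator NRF2 (-0.08, 0.00814) were lower, with adjusted p = 0.0854, 0.395 and 0.518 with an estimated correlation. The glycolytic call ended without 72 h replicate 3 or untreated replicate 2 (at most 0.129), and the ribosome biogenesis call without untreated replicate 2 (0.0706). The nucleotide call ended without 72 h replicate 1, 72 h replicate 2 or untreated replicate 1 (at most 0.149) and with the nuclear RNA score as a covariate, and the NRF2 call without 72 h replicate 1 or untreated replicate 1 (at most 0.356). With the library set as a term the hypoxia call ended (0.0863), as did those of nucleotide metabolism (0.264), NRF2 targets (0.315) and ribosome biogenesis (0.256). All 3 libraries at 72 h had a higher antisense index (0.426 to 0.478) than the untreated libraries (0.304 and 0.315).

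**Figure D2:**
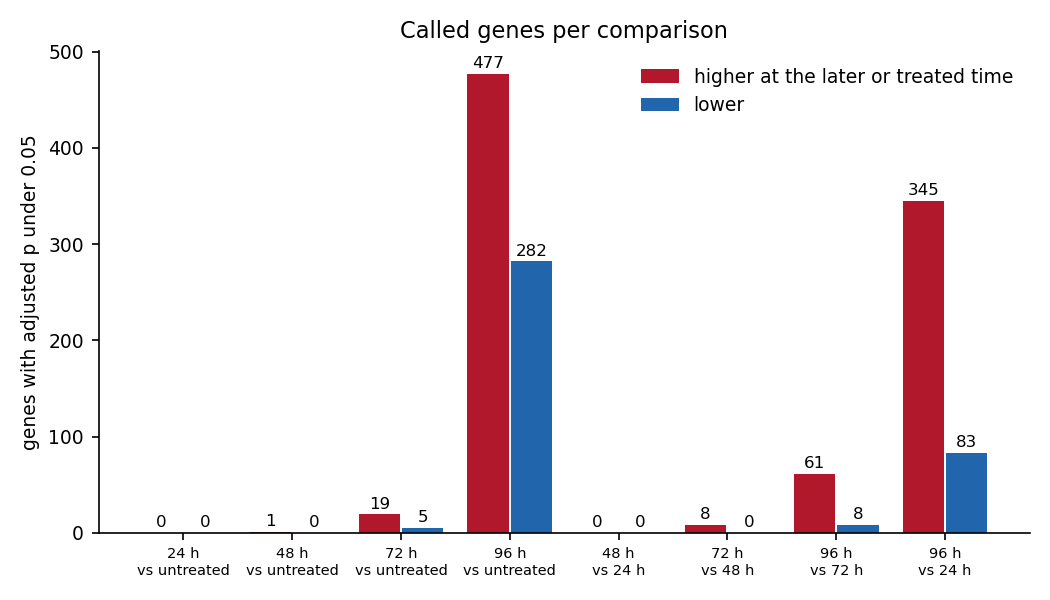
Number of genes called higher and lower in each comparison at an adjusted p under 0.05 (edgeR, 13371 genes). Against untreated cells the counts were 0 at 24 h, 1 at 48 h, 24 at 72 h and 759 at 96 h, and against 24 h the count at 96 h was 428.

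At 96 h, the longest exposure, 477 genes rose and 282 fell against untreated cells. Most changes were modest, with a median size of 0.37 on the log2 scale, and 24 genes rose and 5 fell by at least 2-fold. By the fixed rule, the largest rises were those of CA9, a carbonic anhydrase induced by low oxygen (1.56 ± 0.26), the actin-associated gene SYNPO2L (1.32 ± 0.29), the fibrillar collagen COL11A1 (1.29 ± 0.14), GDF15 (1.29 ± 0.14), the matrix proteoglycan FMOD (to 3.34 ± 1.09 CPM from 1.40 ± 0.14 CPM, SD) and SUSD2 (1.17 ± 0.23). The largest falls were those of E2F2 (-1.50 ± 0.20; hg19 chromosome 1, 23832920 to 23857712), FAM111B (-1.14 ± 0.10), the matrix metalloproteinase MMP3 (-1.10 ± 0.24), the nicotinic receptor subunit CHRNA5 (-1.03 ± 0.29), TBC1D8 (-0.99 ± 0.28) and the activin receptor ACVR2B (-0.85 ± 0.24). Adjusted p was 0.0405 or less for each of these 12 genes. All 759 called genes had the 3 treated libraries on one side of both untreated ones, as did 40.3% of all tested genes, where chance gives 20%. At an unadjusted p under 0.05 there were 2649 genes.

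These counts depended on single libraries. The number called was 265 without untreated replicate 1, 174 without untreated replicate 2, 425 without 96 h replicate 1 and 431 without 96 h replicate 3. The calls of SYNPO2L ended without untreated replicate 1 (adjusted p = 0.160), those of SUSD2 and MMP3 without either untreated library (at most 0.0671 and 0.0769), and those of FMOD and CHRNA5 without either untreated library or 96 h replicate 1 or 3 (at most 0.216 and 0.378). TBC1D8 lost its call without either untreated library or 96 h replicate 1 or 2 (at most 0.300), and ACVR2B without either untreated library, 72 h replicate 1 or 2, or 96 h replicate 2 or 3 (at most 0.396). With only the compared groups in the fit 1646 genes were called, with MALAT1 and 3 other nuclear RNAs as a covariate 1848, and with the library set as a term 121. With the set and the nuclear RNA score together 1008 were called, 455 of the 759 among them. The replicate number as a block gave 687, with 638 of the 759 among them. The fit with the set alone gave all 759 genes the same sign, a median of 0.41 in the direction of the call against 0.37 without it, and a median SE of 0.13 against 0.08. That term rests on 48 h replicate 3 alone, so the kept signs and sizes do not show that the set was adjusted for. The antisense index was 0.408 to 0.479 in the 96 h libraries, against 0.304 and 0.315 in untreated cells. Of the 46 genes named by rule and called at 96 h, 15 kept their call under every alternative run, and these were CDKN1A, GDF15, BBC3, DDIT4, STC2, NDRG1, LOX, COL11A1, ELN, ACTA2, ACTG2, MCM4, MCM6, MCM7 and FAM111B. FMOD, CHRNA5 and ACVR2B also lost their calls with limma-voom. With the library set as a term, only COL11A1, GDF15 and FAM111B of the largest rises and falls kept theirs (largest adjusted p = 0.0497). E2F2 stood at -1.37 ± 0.34 (adjusted p = 0.0609) and CA9 at 1.83 ± 0.47 (0.0761). For SYNPO2L, FMOD, SUSD2, MMP3, CHRNA5, TBC1D8 and ACVR2B adjusted p was 0.110 to 0.493 with that term.

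Among p53 targets at 96 h, 22 of 38 rose and 1 fell (29 and 1 when adjusted over the list alone), with a median of 0.34. CDKN1A rose to 879 CPM from 439.7 CPM (1.00 ± 0.08, adjusted p = 3.05e-07), BBC3 rose by 1.05 ± 0.14 (adjusted p = 8.85e-05), and GDF15 (hg19 chromosome 19, 18496770 to 18499987), which ATF4 also activates, rose to 39 CPM from 15.9 CPM (adjusted p = 2.34e-05). MDM2, the ubiquitin ligase that restrains p53, rose by 0.33 ± 0.07 (adjusted p = 0.00480), a call lost without untreated replicate 1 (0.104). The member that fell was KITLG, the ligand of the KIT receptor, named after its value was seen (-0.25 ± 0.07, adjusted p = 0.0335), and its call ended without either untreated library or 96 h replicate 1 or 3 (at most 0.241). MDM2 and KITLG were also not called with the library set as a term (0.27 ± 0.11, adjusted p = 0.298, and -0.38 ± 0.11, adjusted p = 0.110). For the p53 list, adjusted p = 3.13e-21, and 5.75e-05 with an estimated correlation. The antisense index also moved with this time, as given above.

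Some genes of DNA replication, mitosis and ribosome production fell at 96 h. Of 52 DNA replication and G1/S genes, 27 fell (38 when adjusted over the list alone), with a median of -0.36 (adjusted p = 2.03e-25, and 0.00624 with an estimated correlation). The helicase subunits MCM7 (hg19 chromosome 7, 99690351 to 99699563), MCM4 and MCM6 fell by 0.53 ± 0.06, 0.50 ± 0.06 and 0.55 ± 0.07 (largest adjusted p = 2.94e-05). Of 37 ribosome biogenesis genes, 7 fell (16 over the list alone) and 37 lay below 0, with a median of -0.19 (adjusted p = 2.38e-11, and 0.00624 with an estimated correlation). NCL, the nucleolar protein nucleolin, fell by 0.26 ± 0.05, a call lost without either untreated library (at most adjusted p = 0.0652). Of 60 G2/M genes, 7 fell (9 over the list alone; median -0.12, adjusted p = 1.08e-07, and adjusted p = 0.395 with an estimated correlation). FOXM1, a mitotic transcription factor, fell by 0.27 ± 0.06 (adjusted p = 0.00712), a call lost without 96 h replicate 1 or either untreated library (at most 0.0910). The proliferation marker MKI67 fell by 0.58 ± 0.15 (adjusted p = 0.0458). That call ended without any 1 of 10 libraries, namely 24 h replicate 1, all 3 at 48 h, 72 h replicate 1, all 3 at 96 h and both untreated (at most 0.349), and without the filter on low counts. NCL (-0.32 ± 0.09, adjusted p = 0.110), FOXM1 (-0.30 ± 0.10, 0.161) and MKI67 (-0.64 ± 0.26, 0.317) were not called with the library set as a term. In nucleotide metabolism, 2 of 36 genes fell, RRM2, a ribonucleotide reductase subunit (-0.26 ± 0.07), and the nucleoside transporter SLC29A1 (-0.34 ± 0.10), and adjusted p = 0.00975 for the list became adjusted p = 0.340 with an estimated correlation. Neither gene was called with the library set as a term (adjusted p = 0.312 and 0.451). The list lost its call without untreated replicate 1 (0.0536), RRM2 without either untreated library or 96 h replicate 1 or 3 (at most 0.244), and SLC29A1 without any 1 of the 3 libraries at 96 h or either untreated library (at most 0.240), with DESeq2 and without the filter.

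Amino acid response, hypoxia-response and glycolytic genes rose as groups, though not every member did. Of 51 ATF4 targets, 27 rose (39 rose and 1 fell over the list alone), with a median of 0.28 (adjusted p = 1.48e-21, and 0.00356 with an estimated correlation). DDIT4, an inhibitor of mTORC1 signaling, rose by 0.88 ± 0.08, the secreted glycoprotein STC2 by 0.55 ± 0.06, asparagine synthetase (ASNS) by 0.41 ± 0.07 and ATF4 itself by 0.32 ± 0.06 (adjusted p = 0.00114, and 0.0508 without untreated replicate 1). The ER stress gene DDIT3 stood at 0.43 ± 0.14 (adjusted p = 0.0768). Of 25 hypoxia-response genes, 15 rose and 1 fell (18 and 1 over the list alone), with a median of 0.36 (adjusted p = 4.21e-15, and 0.00101 with an estimated correlation). NDRG1 rose by 0.52 ± 0.06 and LOX, a collagen cross-linking enzyme, by 0.51 ± 0.06. The member that fell, singled out after its value was seen, was the secreted glycoprotein STC1 (-0.37 ± 0.08), whose call ended without 96 h replicate 1 or either untreated library (at most adjusted p = 0.0831). Of 25 glycolytic genes, 14 rose (17 over the list alone), with a median of 0.23 (adjusted p = 6.77e-09, and 0.0367 with an estimated correlation). They included the glucose transporter SLC2A1 (0.43 ± 0.07), aldolase C (ALDOC, 0.58 ± 0.09) and phosphoglycerate kinase (PGK1, 0.35 ± 0.06). With the library set as a term, 7 calls ended as SEs grew: ATF4 stood at 0.36 ± 0.10 (adjusted p = 0.0906), STC1 at -0.46 ± 0.14 (0.147), CA9 at 1.83 ± 0.47 (0.0761), SLC2A1 at 0.48 ± 0.12 (0.0517), ALDOC at 0.64 ± 0.16 (0.0732), PGK1 at 0.35 ± 0.10 (0.114) and ASNS at 0.29 ± 0.11 (0.230), the last also at a smaller fold. With the nuclear RNA score added to that term all 7 were called (largest adjusted p = 0.0471).

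Matrix, contractile and inflammatory lists were called by camera at 96 h with the preset correlation but not with an estimated one. The rotation test fry also called them (adjusted p = 6.32e-04, 1.85e-04 and 1.06e-04). Of 44 collagen and matrix genes, 23 rose (29 rose and 1 fell over the list alone), with a median of 0.30 (adjusted p = 5.08e-14, and adjusted p = 0.0625 with an estimated correlation). COL11A1 rose to 29.5 CPM from 12 CPM (adjusted p = 7.53e-06) and ELN by 0.85 ± 0.09. Of 29 contractile genes, 13 rose (18 rose and 1 fell over the list alone), with a median of 0.17 (adjusted p = 1.49e-10, and adjusted p = 0.0586 with an estimated correlation). ACTA2 rose to 967 CPM from 473 CPM (1.03 ± 0.08, adjusted p = 3.05e-07), ACTG2 by 0.60 ± 0.07 and tropomyosin 1 (TPM1) by 0.44 ± 0.05, the last not called with the library set as a term (0.36 ± 0.09, adjusted p = 0.0536). Of 25 inflammatory genes, 7 rose and 2 fell (8 and 2 over the list alone), with a median of 0.25 (adjusted p = 0.0148, and adjusted p = 0.0645 with an estimated correlation). The adhesion molecule ICAM1 rose by 0.76 ± 0.12, and the chemokines CCL2 and CXCL12 by 0.64 ± 0.14 and 0.33 ± 0.08, while MMP3 fell as given above. With the library set as a term, ICAM1 stood at 0.71 ± 0.20 (adjusted p = 0.106), CCL2 at 0.58 ± 0.24 (0.285) and CXCL12 at 0.32 ± 0.13 (0.293). CCL2 lost its call without either untreated library (at most 0.101), and CXCL12 without either untreated library or 96 h replicate 2 (at most 0.243).

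Few nuclear genes for mitochondrial function were called at 96 h. Complex I subunits had a median of 0.10, with 0 of 37 passing (adjusted p = 0.0288, and adjusted p = 0.829 with an estimated correlation), a call that ended without 96 h replicate 2, 96 h replicate 3 or untreated replicate 2 (at most 0.172) and with the nuclear RNA score as a covariate. The replicate number as a block ended the complex I call as well (camera adjusted p = 0.116). The medians were 0.04 for 40 complex II to V subunits (adjusted p = 0.198) and -0.02 for 77 mitochondrial ribosomal proteins (adjusted p = 0.478), with 0 genes called in either. Among 37 genes of mtDNA replication, transcription and maintenance, 2 rose and 2 fell (3 and 5 over the list alone), and 27 lay below 0, with a median of -0.09. Singled out after their values were seen, RRM2B rose by 0.33 ± 0.09 and MPV17 by 0.27 ± 0.08 (adjusted p = 0.0402 and 0.0449). Neither was called with the library set as a term (adjusted p = 0.580 and 0.502). The 2 that fell were FEN1, given below, and TFAM. The list was not called by camera (adjusted p = 0.0683, and 0.133 with an estimated correlation) but was lower with fry (adjusted p = 0.00380). TFAM fell by 0.31 ± 0.09 (adjusted p = 0.0449), to 39.4 CPM from 49 CPM. That call ended with DESeq2, with limma-voom and without any 1 of 7 libraries, namely 48 h replicate 1, 72 h replicates 1 and 2, 96 h replicates 1 and 3 and both untreated (at most adjusted p = 0.229). TFAM was also not called with the library set as a term (-0.44 ± 0.15, adjusted p = 0.189). The mtDNA polymerase POLG stood at -0.13 ± 0.13, the mtDNA helicase TWNK at -0.13 ± 0.11, the single-stranded DNA-binding protein SSBP1 at 0.03 ± 0.08 and thymidine kinase 2 (TK2) at -0.04 ± 0.09 (smallest adjusted p = 0.548). Of 32 tricarboxylic acid cycle genes 1 rose (adjusted p = 0.388), and of 24 mitochondrial chaperones and proteases 1 fell (adjusted p = 0.252).

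Other lists were not called at 96 h, apart from cytosolic ribosomal proteins. Those had a median of 0.10 with 1 of 72 rising (adjusted p = 0.00164, and adjusted p = 0.829 with an estimated correlation), a call lost without untreated replicate 2 (0.0677). That 1 gene, RPL23A (0.33 ± 0.08), lost its call without either untreated library or 96 h replicate 3 (at most 0.161). Interferon-stimulated genes had 2 of 48 rising and 2 falling (adjusted p = 0.328), with IFIT1 at -0.25 ± 0.18 and ISG15 at 0.41 ± 0.15. Cholesterol genes had 1 of 25 rising and 1 falling (adjusted p = 0.548). HMGCS1, an enzyme of sterol synthesis, stood at -0.10 ± 0.09. TXNIP, a glucose-responsive thioredoxin inhibitor, stood at -0.25 ± 0.07 (adjusted p = 0.0519). Adjusted p was 0.0770 for NRF2 targets (1 of 26 rising, median -0.09), 0.362 for ER stress genes (2 of 24 rising) and 0.362 for lysosome and autophagy genes (3 of 36 rising, 1 falling). It was 0.216 for immediate early genes (2 of 23 rising, 1 falling), 0.643 for fatty acid synthesis (1 of 17 falling), 0.945 for fatty acid oxidation (1 of 24 falling) and 0.0527 for cytosolic heat shock genes (1 of 19 rising, 6 falling).

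**Figure D3:**
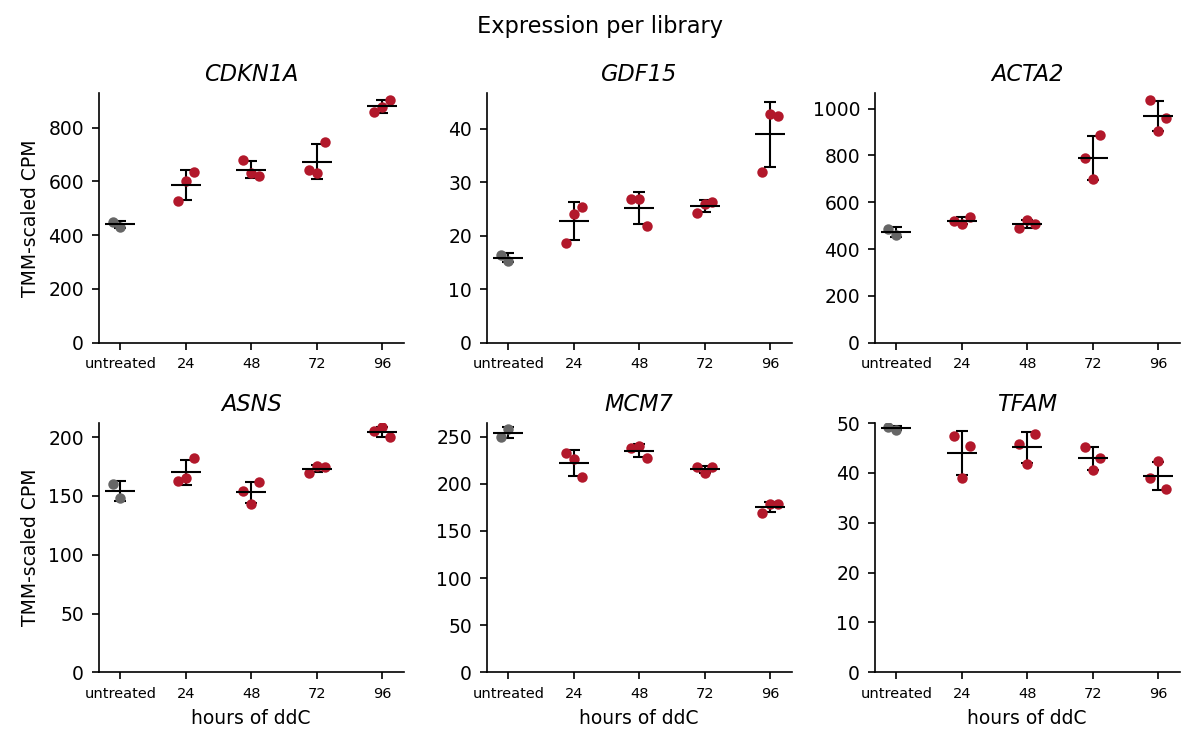
TMM-normalised expression (CPM) of CDKN1A, GDF15, ACTA2, ASNS, MCM7 and TFAM in each library by hours of ddC; points are libraries, bars are group means and error bars are SD (n = 3 treated, n = 2 untreated). CDKN1A stood at 439.7 CPM in untreated cells and 879 CPM at 96 h, and ACTA2 at 473 and 967 CPM.

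**Figure D4:**
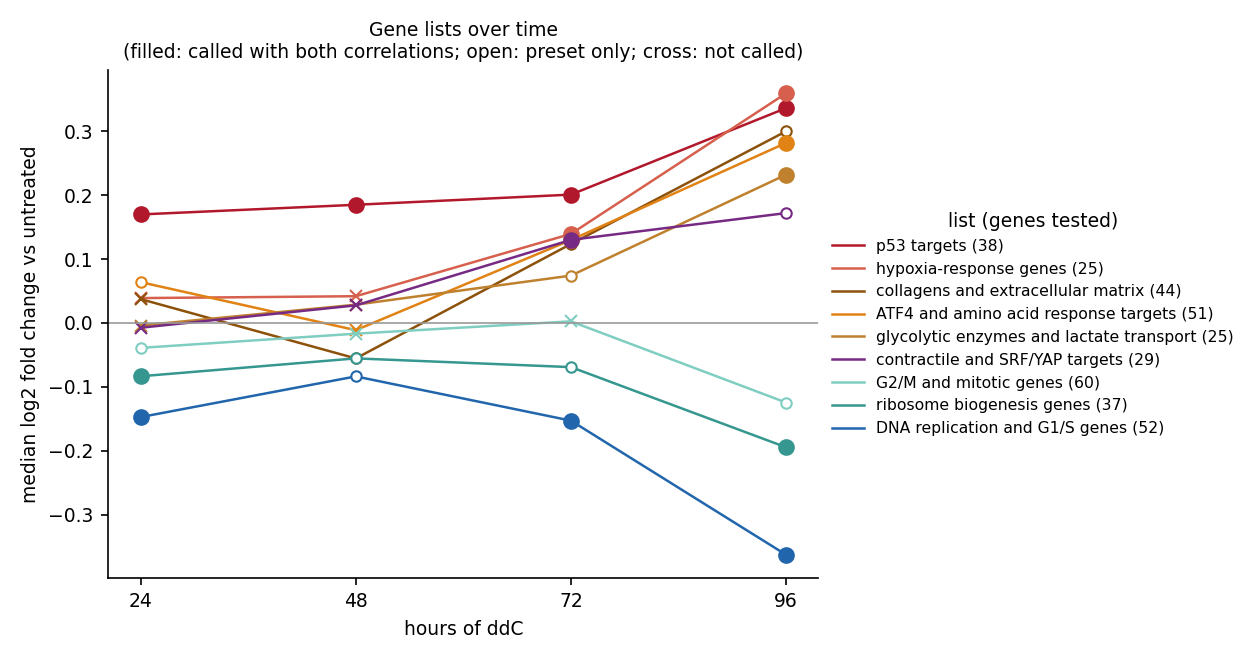
Median log2 fold change against untreated cells of 9 gene lists at 24, 48, 72 and 96 h of ddC. Filled points were called with the preset and the estimated correlation, open points with the preset alone, and crosses were not called; p53 targets ran from 0.17 at 24 h to 0.34 at 96 h, and DNA replication genes from -0.15 to -0.36.

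Comparison of 96 h with 24 h asked which changes differ between late and early exposure, without the untreated libraries (n = 3 and 3). The labels give 1 day for the 24 h libraries and 4 days for the 96 h libraries. With 0 untreated libraries labelled 1, 2 or 3 days, length of exposure and time in culture cannot be told apart here. COL11A1 rose by 1.30 ± 0.12, CA9 by 1.18 ± 0.22, SYNPO2L by 1.28 ± 0.26 and the glycosyltransferase EXTL1 by 1.26 ± 0.28. MMP3 fell by 1.06 ± 0.22, FAM111B by 0.76 ± 0.09, HEY1, a target of Notch signaling, by 0.70 ± 0.15, the receptor ADGRG1 by 0.67 ± 0.16, the aldo-keto reductase AKR1C1 by 0.67 ± 0.14 and the ion channel TRPA1 by 0.62 ± 0.08. Adjusted p was 0.0162 or less for each of these 10 genes. The fixed rule also named SNX22 and the antisense transcript VIM-AS1, which overlap the abundant genes PPIB and VIM on the other strand. SNX22 had 3, 3 and 0 counts in the 24 h libraries against 55, 48 and 54 at 96 h (adjusted p = 0.00476), and VIM-AS1 rose by 1.79 ± 0.28 (adjusted p = 0.00212). Both were higher in the higher-index libraries, and 34 of the 44 SNX22 counts at 48 h came from replicate 3. In all, 345 genes rose and 83 fell, 14 and 2 of them by at least 2-fold, with 2037 at an unadjusted p under 0.05. All 428 called genes had separated libraries, as did 19.0% of all genes, where chance gives 10%.

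Of the 27 lists, 16 differed between 96 h and 24 h, and 8 of these held with an estimated correlation. Those that were higher at 96 h were hypoxia-response genes (median 0.29, adjusted p = 6.01e-20, and 2.02e-04 with an estimated correlation), contractile genes (0.24), glycolytic genes (0.23), matrix genes (0.23), ATF4 targets (0.22) and p53 targets (0.18). DNA replication genes (-0.21, adjusted p = 1.06e-17, and 0.0103 with an estimated correlation) and ribosome biogenesis genes (-0.13) were lower. The gene count was 259 without 24 h replicate 1, 223 without 96 h replicate 1, 262 without 96 h replicate 3 and 37 with the library set as a term, under which 2 of the 12 genes named for this comparison, FAM111B and TRPA1, were still called. With that term all 428 genes kept their sign, with a median of 0.39 against 0.36, and the median SE grew to 0.13 from 0.07. With the nuclear RNA score added to it 437 were called, 193 of the 428 among them. EXTL1 lost its call without 24 h replicate 2 or 3 or 96 h replicate 1 or 3 (at most adjusted p = 0.0818), HEY1 without 96 h replicate 1 or 2 (at most 0.0620), and ADGRG1 without 24 h replicate 2 or 96 h replicate 1 or 3 (at most 0.101).

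Consecutive times were compared to place these changes in time (n = 3 and 3). Here, and across the treated times below, hours of ddC and labelled days rose together, so their effects cannot be told apart. Between 48 h and 72 h, 8 genes rose and 0 fell, all named after their values were seen. The largest rise was that of ACTA2 (0.64 ± 0.07, adjusted p = 1.46e-04), with the matrix or adhesion genes ELN (0.44 ± 0.08), COL4A1 (0.34 ± 0.06), SULF1 (0.37 ± 0.07) and the integrin subunit ITGA1 (0.37 ± 0.06). TAGLN, the serine protease CORIN and the EGF receptor inhibitor ERRFI1 made up the rest, with a largest adjusted p of 0.0330. Of these, ACTA2 alone kept its call without any 1 library (at most 0.00534), and the library set as a term ended all 8 calls (ACTA2 at 0.64 ± 0.10, adjusted p = 0.118). All 8 kept their sign with it, with a median of 0.38 against 0.37 and a median SE of 0.09 against 0.06, and 4 of them were called when the nuclear RNA score was added. Limma-voom ended the calls of all but ACTA2 and ITGA1, and the fit of only the compared groups those of TAGLN, CORIN and ERRFI1. The count was 1 without 48 h replicate 1 or 72 h replicate 1, 3 without 48 h replicate 3 or 72 h replicate 3, 4 without 48 h replicate 2 or 96 h replicate 3, and 16 without 24 h replicate 3. ELN was lost without any 1 of the 3 libraries at 48 h, 72 h replicate 1 or 3, and COL4A1 without 48 h replicates 1 or 3 or any 1 of the 3 at 72 h (at most 0.295 and 0.306). SULF1 and CORIN were lost without any 1 of the 6 compared libraries or 96 h replicate 3, and CORIN also without 96 h replicate 2 (at most 0.364 and 0.359). ITGA1 was lost without 48 h replicate 1 or 72 h replicates 1 or 2 (at most 0.295). TAGLN and ERRFI1 were lost without any 1 of the 3 at 48 h, 72 h replicates 1 or 3 or 96 h replicate 3, and TAGLN also without either untreated library (at most 0.306 and 0.359). On simulated data with no change in this comparison, the test called 6 genes. Between 24 h and 48 h edgeR called 0 genes, with 541 at an unadjusted p under 0.05, while DESeq2 called 1 and limma-voom 0.

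Between 72 h and 96 h, 61 genes rose and 8 fell, with 1544 at an unadjusted p under 0.05. Among genes already named at 96 h, COL11A1 rose by 0.89 ± 0.12 (adjusted p = 6.60e-04), DDIT4 by 0.55 ± 0.07 (adjusted p = 5.68e-04) and NDRG1 by 0.43 ± 0.06 (adjusted p = 6.42e-04), and these 3 kept their calls under every alternative run. CDKN1A rose by 0.38 ± 0.07, STC2 by 0.25 ± 0.05 and ELN by 0.41 ± 0.07, while MCM7 fell by 0.30 ± 0.05 (largest adjusted p = 0.0150). Each of these 4 lost its call without 72 h replicate 1 or 2 or 96 h replicate 1 or 3 (at most 0.127). ACTA2 stood at 0.29 ± 0.07 (adjusted p = 0.0569). The libraries of both times lay in the higher-index set, and with the library set as a term 64 genes were called. Leaving out 48 h replicate 3 also gave 64, as the term here does no more than drop that library. The count was 6 without 72 h replicate 1, 5 without 72 h replicate 2, 243 without 72 h replicate 3, 7 without 96 h replicate 1, 31 without 96 h replicate 2, 21 without 96 h replicate 3 and 118 without 24 h replicate 3.

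Across the 4 treated times together, 368 genes differed, with 1619 at an unadjusted p under 0.05. Of these, 310 were also called at 96 h against 24 h and 295 at 96 h against untreated cells. Among those with the smallest adjusted p were ACTA2 (1.24e-07), ELN (5.81e-07), DDIT4 (8.78e-07) and COL11A1 (1.15e-06). The count was 177, 213 and 206 without 96 h replicates 1, 2 and 3, and 101 with the library set as a term. All 24 genes called at 72 h against untreated cells were also called at 96 h in the same direction, 19 higher and 5 lower, including CDKN1A, ACTA2 and FAM111B. Simulated data with no effect of ddC shared 0.1 and 0 on average. Such counts are near 0 by construction, since few genes are called at either time without an effect, so they do not gauge the overlap. The libraries of 72 h and 96 h also lay in the same higher-index set. Both comparisons used the same 2 untreated libraries, whose chance values alone would give a correlation of 0.610 across genes in simulated data, and the observed correlation was 0.597. The covariance exceeded the simulated one by 0.00869 for 72 h with 96 h and by 0.00620 for 48 h with 96 h, and lay below it for the other 4 pairs of times.

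Markers were examined for RNA of other cell types. Of 15 fibroblast markers at 96 h, 5 rose and 1 fell (adjusted p = 0.0623 for the list), the collagen COL1A2 rising by 0.32 ± 0.05 and the growth factor receptor PDGFRA falling by 0.30 ± 0.07, a call lost without either untreated library or 96 h replicate 1 or 3 (at most adjusted p = 0.160). Of 6 tested epithelial markers, the keratins KRT18 (0.44 ± 0.09) and KRT8 (0.55 ± 0.15) rose, and 5 lay above 0, with a median of 0.50. The list was not called by camera (adjusted p = 0.0623) but was with fry (adjusted p = 0.0249), as was that of fibroblast markers (0.0441), so a change in these markers is not excluded. KRT18 lost its call without either untreated library (at most 0.117), and KRT8 without untreated replicate 2 or 96 h replicate 1 or 3 (at most 0.406) and with DESeq2. With the library set as a term COL1A2 stood at 0.38 ± 0.09 (0.0573), KRT18 at 0.63 ± 0.15 (0.0546), KRT8 at 0.52 ± 0.25 (0.372) and PDGFRA at -0.38 ± 0.13 (0.176). Of 5 tested endothelial markers 0 were called (list adjusted p = 0.837), and of the blood cell markers only CD68 and CORO1A were expressed enough to test, at -0.09 and -0.28 (adjusted p = 0.584 and 0.490).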

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

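The tests of nuclear RNA, library set, time in culture and opposite-strand reads below were chosen after the results were seen, while what the test of GC content and length should show was written before its result was seen and the counts of other splits were planned.

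What singled out the following results is that the change at 96 h differed from that at 24 h by a direct test of 96 h against 24 h (n = 3 and 3). This held for 34 of 67 named genes and 16 of 27 lists. Of the 67 genes, 12 had been named because they changed most in this same comparison and so met it by construction, and of the other 55 it held for 22. Apart from the fixed genes, these 55 had been named for their change at 96 h against untreated cells. That choice used the same 96 h libraries, so this share is not free of selection either. On the log2 scale, 96 h minus 24 h was 4.50 for SNX22, 1.79 for VIM-AS1, 1.30 for COL11A1, 1.28 for SYNPO2L, 1.26 for EXTL1 and 1.18 for CA9. It was 0.90 for ELN, 0.89 for ACTA2, 0.81 for SUSD2, 0.78 for GDF15, 0.68 for ICAM1, 0.65 for DDIT4, 0.58 for CDKN1A, 0.55 for LOX and 0.51 for ACTG2. Smaller rises were 0.48 for STC2, 0.47 for SLC2A1, 0.46 for ALDOC, 0.44 for NDRG1, 0.41 for TPM1, 0.33 for CXCL12, 0.33 for PGK1, 0.27 for ASNS and 0.26 for ATF4. Among falls, the values were -0.33 for MCM4, -0.34 for MCM7, -0.36 for MCM6, -0.37 for TXNIP, -0.62 for TRPA1, -0.67 for AKR1C1, -0.67 for ADGRG1, -0.70 for HEY1, -0.76 for FAM111B and -1.06 for MMP3. The fitted value of SNX22 rests on 24 h libraries with 0 to 3 counts and depends on the prior count.

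Medians of the lists that differed were 0.29 for hypoxia-response genes, 0.24 for contractile genes, 0.23 for glycolytic genes, 0.23 for matrix genes, 0.22 for ATF4 targets, 0.18 for p53 targets, -0.13 for ribosome biogenesis genes and -0.21 for DNA replication genes, which held with an estimated correlation. Another 8 lists did not hold with it, namely inflammatory genes (0.16, adjusted p = 0.0510 with an estimated correlation), cytosolic ribosomal proteins (0.0623, 0.597), immediate early genes (0.0612, 0.313), ER stress genes (0.0607, 0.475), mtDNA maintenance genes (-0.0664, 0.0558), G2/M genes (-0.0945, 0.346), NRF2 targets (-0.11, 0.313) and heat shock genes (-0.11, 0.475).

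At 24 h, p53 targets were higher and DNA replication genes lower as groups with no single gene called. With the nuclear RNA score as a covariate the larger adjusted p of the 2 lists was 3.22e-14, which argues against recovery of nuclear RNA as the whole cause. Of 10000 lists matched on expression, GC content and transcript length, a share of 0.0001, the smallest these draws can give, had medians as far from theirs, which argues against GC content or length. Of the 5 libraries compared, 0 lay in the higher-index library set, so membership of that set cannot account for it, while the smaller difference in index within the lower set was not tested. An early response of these genes to ddC remains as a hypothesis, found and tested on the same data and with only 2 untreated libraries whose time in culture is uncertain, so that a difference in culture may contribute.

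For the 759 genes called at 96 h, the library set cannot be the whole cause, because libraries at 72 h lie in the same set. Among genes called without the 96 h library under test, that library lay beyond the 72 h mean in the direction of the call, with medians of 0.21 (425 genes, 96.7% in that direction), 0.13 (620 genes, 87.3%) and 0.21 (431 genes, 94.9%) for replicates 1, 2 and 3, the lowest being 0.13. A contribution of the set stays open, since a step between 48 h and 72 h coincides with it, and with the set as a term 121 genes were called, the median SE growing to 0.13 from 0.08 while the fold went to 0.41 from 0.37, and 1008 with the nuclear RNA score added to it. The set term rests on 48 h replicate 3 alone, so these fits cannot settle it. Recovery of nuclear RNA is argued against, as 759 of the 759 genes were still called in the same direction with that score as a covariate. Time in culture stays open, because the sample labels give 4 days for both the untreated and the 96 h libraries, which would match them, whereas the design text gives the untreated cells as 0 h, and for the earlier times 0 untreated libraries are labelled 1, 2 or 3 days.

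SNX22 and VIM-AS1 rose between 24 h and 96 h. Leakage of opposite-strand reads at 1 rate for all genes is argued against as the whole of that rise, because SNX22 rose 20.6-fold and VIM-AS1 3.45-fold per partner read against 1.30-fold for other pairs, the smaller ratio to these being 2.65. From untreated cells to 96 h the folds of SNX22 and VIM-AS1 were 3.82 and 2.05 beside 1.44 for other pairs, a ratio of 1.42 for VIM-AS1. The library set remains a candidate explanation, because 48 h replicate 3, alone of its time in the higher-index set, stood above the higher of the other 48 h libraries by 5.25 times for SNX22 and 1.82 times for VIM-AS1, and between 72 h and 96 h, within the set, adjusted p was 0.679 and 0.685. With the set as a term, 96 h minus 24 h went to 1.89 ± 0.85 from 4.50 ± 0.74 for SNX22 and to 0.89 ± 0.37 from 1.79 ± 0.28 for VIM-AS1 (adjusted p = 0.473 and 0.426), so the calls ended with smaller folds and larger SEs, and a response to ddC stays untested beyond this.

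Other ways of splitting the libraries were counted for each comparison of 3 with 3, where 10 splits exist and a share under 0.05 cannot be reached. For 96 h against 24 h the real split gave 428 genes and the highest other 0, so 1 of 10 splits gave as many. For 96 h against 72 h the real split gave 69 and the highest other 0 (1 of 10), and for 72 h against 48 h it gave 8 and the highest other 0 (1 of 10). For 48 h against 24 h the real split gave 0 and the highest other 0, so 10 of 10 gave as many. Across the 4 treated times, 2 of 100 regroupings of the 12 libraries, the real one included, gave as many genes as the real 368, a share under 0.05. The other of these gave 930 genes, which points to a structure of the samples beyond the time groups. In a check made after that count was seen, 88.1% of the variance of the nuclear RNA score lay between its groups, the most of the 99 random regroupings, against 10.4% between the real times. Over all 99, this share and the number of genes had a rank correlation of 0.102, but most regroupings gave 0 genes, so that value rests on ties and cannot show whether they are related. The regrouping with the next most genes (313) had a share of 71.8%, while those with 203 and 134 genes had 27.9% and 7.96%.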

How the results depend on the processing

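The nuclear RNA score, the library set and the restriction to 1 set were alternatives chosen after seeing the data. Every other alternative was planned, and all planned ones were run. Of 5799 values compared for 249 results on named genes, 0 reversed a called direction, 65 changed sign with no call on either side, and DESeq2 gave no adjusted p for 22. Of 122 results on named genes that were called, 76 lost the call without 1 library or more. Median-ratio size factors moved no count of calls by over 1.5 times. Where no construction is named, the cause was not tested.

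Without the filter on low counts the genes called were 1 at 24 h, 3 at 48 h, 47 at 72 h, 20 at 72 h against 48 h and 117 at 96 h against 72 h. DESeq2 gave 1 at 24 h, 57 at 72 h, 1 at 48 h against 24 h, 35 at 72 h against 48 h and 128 at 96 h against 72 h, and the calls shared between 72 h and 96 h were 57 against 24. Limma-voom gave 0 at 48 h and 2 at 72 h against 48 h. With only the compared groups in the fit, the dispersion rests on fewer libraries, and 7 genes were called at 72 h and 1646 at 96 h.

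With the nuclear RNA score as a covariate the counts were 1, 34, 247 and 1848 at 24, 48, 72 and 96 h, 3 at 48 h against 24 h, 67 at 72 h against 48 h, 248 at 96 h against 72 h, 1091 at 96 h against 24 h and 999 across treated times. With the library set as a term they were 2, 0 and 121 at 48, 72 and 96 h, 0 at 72 h against 48 h, 37 at 96 h against 24 h and 101 across treated times, where the SE grew because the set follows time. With both they were 4, 107, 127 and 1008 at 24, 48, 72 and 96 h, 14 at 48 h against 24 h, 15 at 72 h against 48 h, 329 at 96 h against 72 h, 437 at 96 h against 24 h and 617 across treated times, with 4 lists at 48 h. Within the lower-index libraries 0 genes were called at 48 h, and within the higher-index libraries 0 at 72 h against 48 h, where 1 library at 48 h remained.

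For lists, an estimated correlation left 4, 1, 5 and 6 called at 24, 48, 72 and 96 h, and fry gave 5, 1, 6 and 11, with 10 of the 11 at 96 h among the 13 called by camera and mtDNA maintenance as the other.

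Leaving out 1 library gave 0 to 1 genes at 24 h, 0 to 2 at 48 h, 1 to 35 at 72 h and 174 to 1034 at 96 h. It gave 0 to 0 at 48 h against 24 h, 1 to 16 at 72 h against 48 h, 5 to 243 at 96 h against 72 h, 223 to 545 at 96 h against 24 h and 177 to 497 across treated times. Lists called ranged from 6 to 12, 3 to 9, 8 to 11 and 12 to 14 at 24, 48, 72 and 96 h. Where 1 untreated library is left, it is assumed to vary like the other groups.

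The replicate number as a block gave 0, 1, 25 and 687 genes at 24, 48, 72 and 96 h, 0 at 48 h against 24 h, 15 at 72 h against 48 h, 102 at 96 h against 72 h, 478 at 96 h against 24 h and 406 across treated times, with 7, 5, 11 and 14 lists. The data did not show that the numbers pair the libraries. Of 26 pairs with the same number 11 had a correlation of residuals over 0.1 (-0.36 to 0.61), and 4 of 12 treated libraries were closest to their own number. Variation in nuclear RNA was not taken out of these residuals, so a pairing is not excluded. The pairs include untreated libraries by the number in their titles, which the labels do not tie to the treated replicates. Of the smallest changes simulated at 96 h, 28% were recovered, so a gene not called is not shown to be unchanged.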

Other observations

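All genes in this part were singled out after their values were seen. Cytosolic heat shock genes were not called as a list at 96 h (adjusted p = 0.0527; median -0.18, mean -0.04), with 6 of 19 falling and 1 rising, and 9 and 5 when adjusted over the list alone. HSPH1, a nucleotide exchange factor of HSP70, fell by 0.39 ± 0.06 (adjusted p = 5.50e-04; n = 3 and 2) and kept its call under every alternative run. The constitutive chaperone HSP90AB1 fell by 0.26 ± 0.05 (adjusted p = 0.00363, and 0.0568 without untreated replicate 1) and its inducible relative HSP90AA1 by 0.26 ± 0.06 (adjusted p = 0.0150), a call lost without 96 h replicate 3 or either untreated library (at most 0.158). The small heat shock protein HSPB8 rose by 0.40 ± 0.10 (adjusted p = 0.0238), a call lost without 96 h replicate 1 or 3 or either untreated library (at most 0.315). The mitochondrial chaperonin HSPD1 fell by 0.29 ± 0.06 (adjusted p = 0.00896), a call lost without either untreated library (at most 0.112). With the library set as a term these last 4 genes were not called, HSP90AB1 at -0.31 ± 0.09 (0.111), HSP90AA1 at -0.33 ± 0.10 (0.159), HSPB8 at 0.32 ± 0.17 (0.447) and HSPD1 at -0.37 ± 0.11 (0.111).

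Several single genes passed the test at 96 h in lists that were not called, 2 of them (ATF3 and FEN1) being members of a called list as well. The stress-induced transcription factor ATF3 rose by 1.09 ± 0.17 (adjusted p = 3.21e-04), and stood at 0.79 ± 0.26 with the library set as a term (0.170). FEN1, a flap endonuclease of nuclear and mitochondrial DNA replication, fell by 0.44 ± 0.07 (adjusted p = 6.54e-04), and stood at -0.41 ± 0.12 with that term (0.124). CPT1A, which controls entry of fatty acids into mitochondria, fell by 0.38 ± 0.07 (adjusted p = 0.00204), and stood at -0.43 ± 0.12 with that term (0.0918). ACACA, the acetyl-CoA carboxylase of fatty acid synthesis, fell by 0.41 ± 0.09 (adjusted p = 0.0109), a call lost without 96 h replicate 3 or untreated replicate 2 (at most 0.2002) and with that term (-0.36 ± 0.16, adjusted p = 0.318). The heme oxygenase HMOX1 rose by 0.40 ± 0.07 (adjusted p = 0.00175; 0.0695 without untreated replicate 2), while the median of NRF2 targets was -0.09.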
